A study of Mus musculus with 12 samples.

How the data were processed

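Gene expression was measured in mouse CD8+ T cells with 12 Agilent 1-colour arrays, each hybridized with Cy3-labelled complementary RNA from 1 sample. Per the labels, all samples came from female C57BL/6 mice, the cells were purified with magnetic beads and then by flow cytometry, and the genotypes were wild type (WT), AID KO and uMT. The uMT mice lack mature B cells because the membrane form of the mu heavy chain is disrupted. Total CD8+ T cells came from peripheral lymph nodes (PLN) or mesenteric lymph nodes (MLN), which drain the gut, and naive CD8+ T cells with low CD44 came from PLN and were sorted into Sca1p and Sca1m fractions, read here as Sca-1 positive and negative from the sorting protocol in the labels. The labels do not say that the samples are separate animals, and the submitters describe the design as having no replicates. P-values therefore measure how far these samples depart from the additive terms of the fit described below, and not a spread between replicates.

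The deposited scanner files hold, per the file headers, the intensity of each spot as extracted by Agilent Feature Extraction 11.0.1.1, which the submitters' processing notes also name. The processed intensity is subtracted for background and corrected for spatial trends by that software, and it is not normalized between arrays. The deposited files also hold other values, namely flags of 0 or 1 for spots that are well above background, saturated, uneven or outlying. The deposited series matrix holds log2 values. Compared with the scanner files, its 28384 probes, all matched, followed the log2 processed intensity with a Pearson correlation of 1.00 on each array, and its 4 columns of each slide shared their sorted values, so the authors' table was quantile normalized within each of the 3 slides apart. Its column medians were 9.47, 8.59 and 8.99 on the 3 slides, and 3600, 244 and 2533 probes were blank there. Differences between slides in that table therefore include a difference in scale, and the scanner files were used instead.

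For the results, log2 processed intensities were taken from the scanner files and shifted so that the 75th percentile of each array was equal. Spots with an outlier flag were left out, between 61 and 342 per array, and no spot was saturated. Probes were kept if they were well above background on at least 2 of the 12 arrays. Probes were named through the transcript accession printed on the array and the RefSeq gene table of GRCm38.p6. Of 56605 probes, 32994 had 1 symbol, 0 had several and 23611 stayed unnamed, so those were kept under their probe names. The array's own coordinates belong to an older assembly, so the gene table was used for names and for gene order only and no position is given. The brightest kept probe stood for each gene, which left 25387 features, 13885 of them named genes. No probe could be named as Ighm, so that gene is not reported.

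Differences were tested with limma 3.58.1 in R 4.3.3, in 1 fit over all 12 arrays with terms for lymph node site, slide, AID KO and uMT in total cells, and for uMT, Sca1p and their own intercept in naive cells. That left 4 residual degrees of freedom, or 3 in the fits with an interaction term. Moderated tests were two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. Values after ± are standard errors of the fit. The naive arrays stand on a slide of their own, so naive and total cells were not compared. The slides hold both genotype classes of total cells. The labels name the corresponding control only for PLN, and each MLN array was set against the WT MLN array of its slide. Where all arrays of 1 group were not well above background, the difference is given as a bound, computed from the lowest signal called well above background. Comparisons, tests, gene lists and the rule for named genes were fixed before the data were examined. The rule names the 8 genes with the largest rise and the 8 with the largest fall past the threshold (3 and 3 in the minor comparisons). Their single-array differences must all have that sign. Where fewer passed, it fills up with the lowest p. It leaves out clone names and the genes on the sex-linked list, and adds Ly6a and up to 3 members of each list. A further gene that the rule names is not reported here.

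The 23 lists were CD8 T cell identity, naive and quiescence, effector and memory CD8, activation and inhibitory receptors, type I interferon response, interferon-gamma response and antigen presentation, Ly6 family, proliferation, immediate early and stress, mucosal homing and residency, glycolysis, cholesterol synthesis, ribosomal proteins, B cells, plasma cells and switched immunoglobulin, CD4 T cells, NK and innate-like lymphocytes, macrophages and monocytes, dendritic cells, neutrophils, stroma and endothelium, erythroid cells, and sex-linked genes. Some genes stand on more than 1 list. Lists were tested with camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. No list call at the preset correlation held with the estimated one. Members were also counted when adjusted over the list alone. The similarity of the 2 genotype effects was computed across genes and set against simulated data with shared controls.

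Alternatives were normexp background correction with an offset of 50 followed by quantile normalization, quantile normalization alone, the series matrix, no filter on dim probes, a filter requiring all 12 arrays, no slide term, slide as a random block, matched pair blocks, separate fits of total and naive arrays, the mean of all probes of a gene, a variance trend with intensity, other sizes of the Sca1 lists, and leaving out each array in turn. The files lack the mean spot signal, so normexp used the median spot signal and median local background. The offset shrinks differences of dim genes. A single coefficient for both genotypes and the genotype effect within each site were added after seeing the data. The fit was tested on simulated data with the spread of these arrays, where 89.9% of 4-fold changes and 40.8% of 2-fold changes were recovered for knockouts versus WT, while 0 of 72 4-fold differences were recovered for each interaction test. The number of arrays limits the precision. Tables were prepared with Python 3.11.15 and pandas 2.3.3 and plots with matplotlib 3.10.9.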

Results

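The 12 arrays comprised 2 WT PLN, 2 WT MLN, and 1 each of AID KO PLN, AID KO MLN, uMT PLN and uMT MLN for total CD8+ T cells, and 1 each of Sca1p AID KO, Sca1m AID KO, Sca1p uMT and Sca1m uMT for naive PLN cells. Between 50.1% and 56.8% of the spots on an array were well above background, and the 75th percentile of the processed intensity ranged from 431.5 to 786.9. Correlations across genes between total-cell arrays were 0.983 to 0.992 within a slide and 0.979 to 0.988 across slides, and WT arrays of 1 site correlated at 0.982 to 0.987. The first principal component held 42.8% of the variance and separated the slide of naive arrays from the others. Ly6a, which encodes Sca-1, followed the sort labels, at 3.87 and 3.40 log2 units above the array's 75th percentile in the 2 Sca1p arrays and 0.03 and -0.10 in the 2 Sca1m arrays. Genotypes are given as the submitters labelled them, and every direction for AID KO refers to arrays labelled AID KO.

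**Figure D1:**
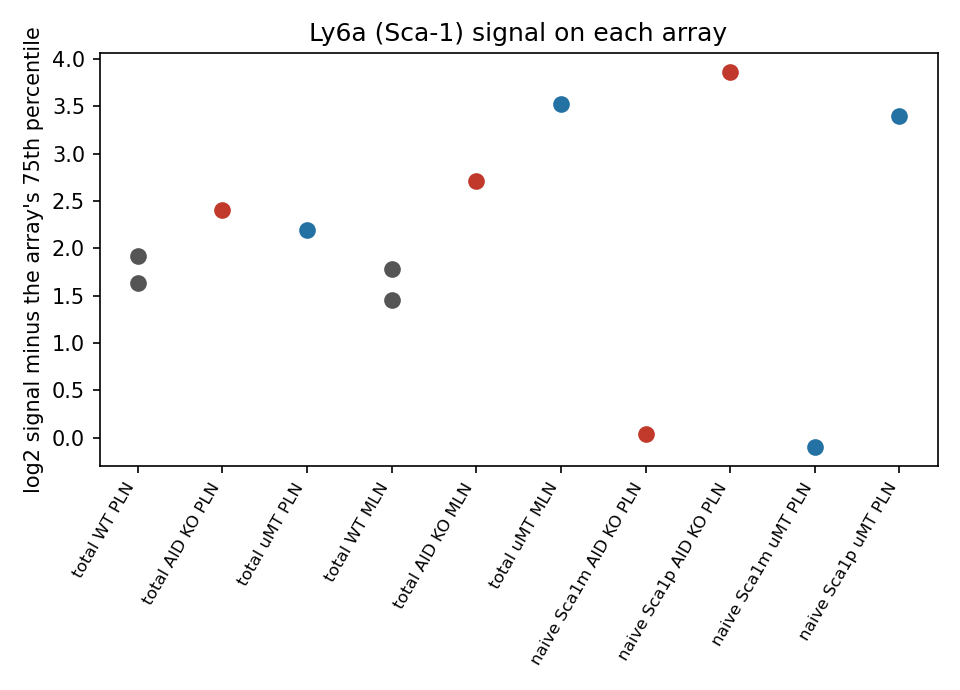
Level of Ly6a on each of the 12 arrays, in log2 units relative to the array's 75th percentile, with groups along the horizontal axis and 1 point per array (grey, WT; red, AID KO; blue, uMT), all well above background. It is lowest on the 2 naive Sca1m arrays, at 0.03 and -0.10.

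The series title concerns CD8+ T cells of mice whose genotypes affect B cells. The first comparison takes the mean of the AID KO and uMT differences from WT. A change in 1 genotype alone can carry that mean, so it does not test what both share. In knockouts versus WT, total cells (4 against 4 arrays), Dusp4, a phosphatase that restrains MAP kinases, fell by 2.08 ± 0.17 on the log2 scale (adjusted p = 0.0349), and Nr4a2 and Nr4a1, nuclear receptors induced by antigen receptor signals, fell by 1.28 ± 0.16 (adjusted p = 0.049) and 1.21 ± 0.13 (adjusted p = 0.0376). The AP-1 partners Maff and Fosl2 fell by 1.77 ± 0.19 and 0.90 ± 0.07 (adjusted p = 0.035 and 0.0215), all with 4 of 4 single-array differences negative. The arrays labelled AID KO carried the larger part of these falls, at -2.50, -2.16, -1.66, -2.34 and -1.34 for Dusp4, Nr4a2, Nr4a1, Maff and Fosl2 against WT, while in uMT the values were -1.67, -0.41, -0.76, -1.20 and -0.46 and none passed, with adjusted p between 0.101 and 0.335. Utp14b fell by 1.66 ± 0.08 and Fam83e by 1.79 ± 0.07 (adjusted p = 0.00619 and 0.0048). Mtus2 and Trnp1 rose by 1.31 ± 0.08 and 1.16 ± 0.08 (adjusted p = 0.014 and 0.0143), again in 4 of 4 pairs. The naming rule requires 1 sign in all pairs of the largest rises and falls. Of all 141 features that passed, 130 had it.

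In total 141 features passed in knockouts versus WT, 44 higher and 97 lower, and 71 of them were named genes. The other named rises were Sly (at least 1.75-fold), Vaultrc5 (1.04), Ttll9 (0.97), Eps8l1 (0.84), Itga7 (0.83) and Zmynd12 (0.77). Sly belongs to a multicopy family of the Y chromosome, and all samples are labelled female, so its probe cannot be read as that gene. The other named falls were Mc1r (-1.80), Guca2a (-1.72), Gp5 (at least 1.12-fold lower) and Stxbp4 (at least 1.69-fold lower), with adjusted p between 0.0123 and 0.0484 over these 10 genes. P2rx7, an ATP receptor of mucosal T cells, fell by 0.55 ± 0.07 (adjusted p = 0.049). Ly6a was higher by 1.01 ± 0.22 in 4 of 4 pairs (range 0.49 to 1.74) but did not pass (adjusted p = 0.109). Without 1 array the count was 0 (AID KO PLN or AID KO MLN), 1 (WT PLN replicate 1, WT MLN replicate 1, WT MLN replicate 2 or uMT MLN), 3 (WT PLN replicate 2), 28 (uMT PLN) or 46 (any naive array, which removes a residual degree of freedom), and no gene named here kept its call in every case. The count was 222 higher and 192 lower with normexp, and 313 and 228 in the series matrix, against 44 and 97. With each knockout array blocked with the WT array of its site and slide it was 11, and 9 of these were among the 141.

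The lists describe the same comparison, knockouts versus WT, by group. Of the 44 tested type I interferon response genes, 41 were higher in the knockouts, with a median of 0.51, but 0 passed singly or when adjusted over the list alone (list adjusted p = 6.99e-08; adjusted p = 0.574 with an estimated correlation). This rise came from the MLN arrays. Against the WT array of the same slide, the list median was 0.83 in AID KO MLN and 1.26 in uMT MLN. It was -0.20 in AID KO PLN and -0.02 in uMT PLN. The 22 immediate early and stress genes had a median of -0.25, with 1 down and 8 down and 1 up when adjusted over the list alone (adjusted p = 0.00027; adjusted p = 0.572 with an estimated correlation). It rests on the arrays labelled AID KO, since the median was -0.40 in AID KO versus WT and 0.18 in uMT versus WT, with 17 of 22 higher in uMT (adjusted p = 0.0533). The 24 activation and inhibitory receptors had 2 down (3 adjusted over the list alone), a median of -0.04 and adjusted p = 0.238. The 33 proliferation genes had a median of -0.15 and 0 passed, with 1 down when adjusted over the list alone (adjusted p = 0.00027; adjusted p = 0.574 with an estimated correlation). The 30 interferon-gamma response and antigen presentation genes had a median of 0.16 (adjusted p = 0.00027; adjusted p = 0.593 with an estimated correlation), a call lost without uMT MLN (adjusted p = 0.24) or AID KO MLN (0.0833). The Ly6 family (9 genes, median 0.15, adjusted p = 0.0492), cholesterol synthesis (17 genes, -0.11, 0.0272) and erythroid cells (5 genes, 0.80, 0.0251) were called too, each with adjusted p = 0.574 with an estimated correlation. The erythroid median was -0.21 in AID KO versus WT, with 1 of 5 higher, and 1.77 in uMT versus WT, with 5 of 5 higher. Each of these 3 calls was lost when any 1 of several arrays was left out. That of the Ly6 family list, knockouts versus WT, was lost without WT MLN replicate 1, WT MLN replicate 2, uMT MLN or AID KO MLN (adjusted p = 0.138, 0.126, 0.416 and 0.158). That of the cholesterol synthesis list, knockouts versus WT, was lost without WT PLN replicate 1, AID KO PLN, WT MLN replicate 1 or uMT MLN (0.0583, 0.0702, 0.0591 and 0.213), and that of the erythroid cells list, knockouts versus WT, without WT PLN replicate 1, AID KO PLN, uMT MLN or uMT PLN (0.0505, 0.143, 0.0641 and 0.0544).

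The remaining lists were not called in knockouts versus WT. Among groups of T cell genes, the medians were 0.03 for CD8 T cell identity (14 genes, adjusted p = 0.473), -0.01 for naive and quiescence (22 genes, 0.672), 0.06 for effector and memory CD8 (39 genes, 0.127), -0.06 for mucosal homing and residency (19 genes, 0.473), -0.02 for glycolysis (16 genes, 0.388) and 0.07 for ribosomal proteins (35 genes, 0.121). Adjusted over the list alone, 1 naive and quiescence gene was up, 8 effector and memory CD8 genes were up and 1 down, 1 mucosal gene was down, 1 glycolysis gene was down and 2 cholesterol synthesis genes were down. Among markers of other cells, the medians were 0.07 for B cells (19 genes, adjusted p = 0.286), -0.32 for plasma cells and switched immunoglobulin (5 genes, 0.127), 0.14 for CD4 T cells (8 genes, 0.181), 0.10 for NK and innate-like lymphocytes (12 genes, 0.388), -0.20 for macrophages and monocytes (7 genes, 0.11), 0.05 for dendritic cells (8 genes, 0.286), -0.17 for neutrophils (6 genes, 0.127) and -0.06 for stroma and endothelium (5 genes, 0.889). Of the sex-linked genes only Xist was tested, at -0.43 (0.238).

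Arrays labelled AID KO were then compared with WT (2 against 4 arrays). In AID KO versus WT, Pianp rose by 6.09 ± 0.25 (adjusted p = 0.00416) and Ppfibp1 by 2.69 ± 0.14 (adjusted p = 0.00434). The second of the 2 Pianp probes differed less, at -3.07 and -2.98 in the AID KO arrays against -5.01, -3.60, -5.31 and -4.38 in WT, and the Pianp log2 difference, AID KO versus WT, was 3.82 with the mean of both. Klk1b22 fell by 5.33 ± 0.26 (adjusted p = 0.00631) and Klk1b24 by 3.80 ± 0.19 (adjusted p = 0.00434), and Klk1b27 was at least 6.83-fold lower, and probes of these close paralogs of the tissue kallikrein family may share signal. Among T cell genes, Cd27, a costimulatory receptor of the naive and quiescence list, rose by 0.88 ± 0.10 (adjusted p = 0.0296), Klrk1, which encodes the activating receptor NKG2D, rose by 2.09 ± 0.25 (adjusted p = 0.032), and the cytokine gene Ifng fell by 1.47 ± 0.16 (adjusted p = 0.0254). The activation list had 4 down, among them Nr4a2 (-2.16), Nr4a1 (-1.66) and the inhibitory receptor Tigit (at least 1.86-fold lower). Ly6a was higher by 0.86 ± 0.27 (adjusted p = 0.231).

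Immediate early and stress genes were lower as a group in AID KO versus WT. Of 22 members 7 fell and 15 did not pass, 13 were down when adjusted over the list alone, and the median was -0.40 (adjusted p = 2.49e-12; adjusted p = 0.0763 with an estimated correlation). Dusp1, a MAP kinase phosphatase, fell by 1.66 ± 0.10 (adjusted p = 0.00492), the transcription factor Klf4 by 1.70 ± 0.16 (adjusted p = 0.0182), and Atf3 was at least 2.72-fold lower (adjusted p = 0.0452). Against the WT array of the same slide the list median was -0.71 in PLN and -0.43 in MLN, while the 2 WT arrays of a site differed by 0.08 and -0.05. Type I interferon response genes had a median of 0.36 with 0 passed (adjusted p = 0.000783; adjusted p = 0.952 with an estimated correlation), a call lost without WT MLN replicate 1 (adjusted p = 0.072) or WT MLN replicate 2 (0.123), and the sign turned without AID KO MLN, at -0.20. Markers of B cells moved in the same samples, with 17 of 19 higher, a median of 0.36 and 0 passed (adjusted p = 0.011; adjusted p = 0.92 with an estimated correlation), a call lost without AID KO MLN (adjusted p = 0.247) and in the series matrix (0.116).

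In AID KO versus WT 229 features passed, 58 higher and 171 lower, of which 136 were named genes. The split was 225 higher and 276 lower with normexp and 258 and 320 in the series matrix. With matched pair blocks 15 features passed, all among the 229. Without WT PLN replicate 1, WT PLN replicate 2, WT MLN replicate 1 or WT MLN replicate 2 the count was 31, 38, 42 and 35, and without AID KO PLN or AID KO MLN it was 1 and 2. Every gene named for this comparison lost its call without 1 or both of the AID KO arrays.

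**Figure D2:**
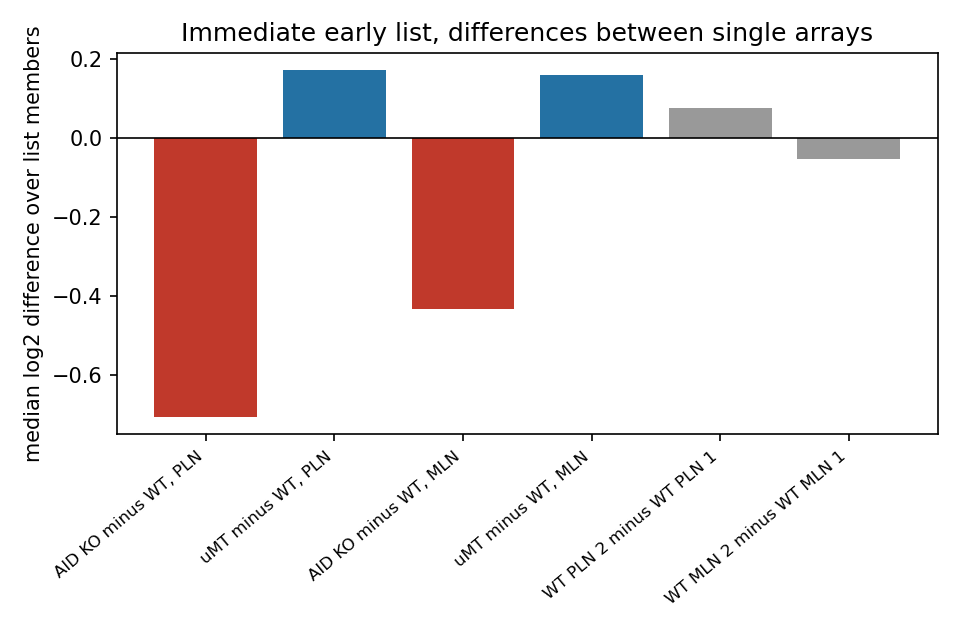
Bars give the median log2 difference over the 22 immediate early and stress genes for each knockout array minus the WT array of its site and slide (red, AID KO; blue, uMT) and between the 2 WT arrays of a site (grey). It is -0.71 and -0.43 in the arrays labelled AID KO and 0.17 and 0.16 in uMT, for PLN and MLN.

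In uMT versus WT (2 against 4 arrays) 9 features passed, 4 higher and 5 lower, and 4547 had an unadjusted p under 0.05 in limma. Trnp1 rose by 1.80 ± 0.10 and Mtus2 by 1.54 ± 0.10 (both adjusted p = 0.0211). Utp14b fell by 1.60 ± 0.10 and Fam83e by 1.49 ± 0.09 (both adjusted p = 0.0211), and Stxbp4 was at least 1.64-fold lower (adjusted p = 0.0431). Ly6a was higher by 1.16 ± 0.27 (adjusted p = 0.152). All 44 type I interferon response genes were higher, with a median of 0.59 and 0 passed (adjusted p = 8.28e-09; adjusted p = 0.539 with an estimated correlation). This rested on the MLN array, since the median was -0.01 without it. Proliferation genes had a median of -0.24 and 0 passed (adjusted p = 6.45e-05; adjusted p = 0.504 with an estimated correlation), and erythroid markers had a median of 1.77 (adjusted p = 5e-04; adjusted p = 0.504 with an estimated correlation). Markers of NK and innate-like lymphocytes (median 0.36, adjusted p = 0.0275) and effector and memory CD8 genes (0.20, 0.00777) were called as well, both with adjusted p = 0.504 with an estimated correlation. The NK and innate-like lymphocytes list, uMT versus WT, lost its call without uMT PLN (adjusted p = 0.212), and the effector and memory CD8 list, uMT versus WT, without uMT MLN (0.112). The lists of interferon-gamma response and antigen presentation (0.18, 5e-04), cholesterol synthesis (-0.18, 0.00777) and ribosomal proteins (0.09, 0.0311) were called with adjusted p = 0.579, 0.504 and 0.697 with an estimated correlation. The cholesterol synthesis list, uMT versus WT, lost its call without uMT MLN (adjusted p = 0.257), and the medians of the interferon-gamma response and antigen presentation list, uMT versus WT, and the ribosomal proteins list, uMT versus WT, turned to -0.04 and -0.13 without it.

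Without 1 array, the count in uMT versus WT was 4 (uMT PLN) or 0 (each of the other 7 total-cell arrays), and it was 8 without any naive array. With matched pair blocks 5 features passed, 0 of them among the 9. The split was 42 higher and 21 lower with normexp and 52 and 21 in the series matrix.

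Across genes, the AID KO and uMT differences from WT correlated at 0.418 (Pearson) and 0.451 (Spearman). They share their WT arrays, which alone gave 0.328 in simulations. With each genotype set only against the WT arrays of its own slide and site, so that no control is shared, the Pearson correlation was 0.241, against -0.002 in simulations. Genes are not independent replicates. Calls in the same direction were shared by 2 features among 58 and 4 rises and by 3 among 171 and 5 falls, with no expected number, since the WT arrays are shared. They were Mtus2 and Gm1976 higher and Adig, Fam83e and Utp14b lower.

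The 2 genotypes were also compared with each other in total cells (2 against 2 arrays). In uMT versus AID KO, total cells, 80 features passed, 58 higher and 22 lower in uMT. Klk1b22 (7.08 ± 0.30), Klk1b24 (5.67 ± 0.22) and Klk1b27 (at least 25.3-fold) were higher, and Pianp (-6.17 ± 0.29 by the brighter of its 2 probes) and Ppfibp1 (-3.14 ± 0.17) were lower, with adjusted p between 0.00241 and 0.00761. Early response genes were higher in uMT. Dusp1 rose by 2.30 ± 0.12, Klf4 by 1.91 ± 0.19, Fos by 1.76 ± 0.13 and the activation marker Cd69 by 1.40 ± 0.10, with adjusted p = 0.00553, 0.0365, 0.0132 and 0.0131. Of the 22 immediate early and stress genes 5 rose, 14 were up and 1 down when adjusted over the list alone, and the median was 0.62 (adjusted p = 2.55e-15; adjusted p = 0.0507 with an estimated correlation). Ly6a differed by 0.30 ± 0.31 (adjusted p = 0.757). For uMT versus AID KO, total cells, the count was 19, 14, 31 and 17 without WT PLN replicate 1, WT PLN replicate 2, WT MLN replicate 1 and WT MLN replicate 2, 7 without AID KO PLN or AID KO MLN, 13 without uMT PLN, 1 without uMT MLN and 35 without any naive array, and no gene named here kept its call throughout. Normexp gave 132 higher and 38 lower, the series matrix 119 and 25, and matched pair blocks 0 and 1.

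The MLN drain the gut, and 4 MLN arrays were compared with 4 PLN arrays across genotypes. In MLN versus PLN 28 features passed, 25 higher and 3 lower in MLN, and all 28, named or not, went 1 way in 4 of 4 pairs. Among the rises were Tgm2, a transglutaminase (at least 6.18-fold), and Dhrs3, a retinaldehyde reductase (3.36 ± 0.16), both with adjusted p = 0.00535. P2rx7 of the mucosal homing and residency list rose by 2.67 ± 0.07 (adjusted p = 0.000751), Dtx4 by 2.75 ± 0.12 (adjusted p = 0.00535), Osgin1 by 2.42 ± 0.15 (adjusted p = 0.00654), Hic1, a transcription factor, by 2.40 ± 0.13 (adjusted p = 0.00535), and Fbln2 at least 1.90-fold (adjusted p = 0.0317). Wnt10a fell by 2.95 ± 0.17 (adjusted p = 0.00573), Gcnt1, an enzyme that builds branched O-glycans, was at least 1.22-fold lower (adjusted p = 0.00535), and Anxa1 was lower and not above background in MLN (adjusted p = 0.0371). S100a4 (-2.02), S100a6 (-0.65), Slc6a19 (-0.72), Igf2os (-0.74) and Niban2 (-1.17) did not pass, with adjusted p between 0.0569 and 0.0662. Ly6a differed by 0.33 ± 0.22 (adjusted p = 0.738).

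Erythroid transcripts were higher in the same MLN arrays. Hbb-b2, a haemoglobin chain, rose at least 2.57-fold (adjusted p = 0.0392), 1 of 5 members passed and 4 were up when adjusted over the list alone, with a median of 3.18 (adjusted p = 4.08e-08; adjusted p = 0.231 with an estimated correlation). In MLN versus PLN immediate early and stress genes had a median of 0.22 with 0 passed (adjusted p = 0.000173; adjusted p = 0.251 with an estimated correlation), a call lost without the filter on dim probes (adjusted p = 0.121). Effector and memory CD8 genes (-0.17, adjusted p = 0.0284), B cell markers (0.09, 0.0284) and markers of NK and innate-like lymphocytes (-0.13, 0.0458) were called too, with adjusted p = 0.785, 0.699 and 0.785 with an estimated correlation, and type I interferon response (0.20, 0.00514) and interferon-gamma response genes (0.08, 0.0114) with 0.826. In the series matrix the effector and memory CD8 list, MLN versus PLN, the B cells list, MLN versus PLN, and the NK and innate-like lymphocytes list, MLN versus PLN, lost their calls (adjusted p = 0.272, 0.427 and 0.369). Without WT PLN replicate 2 they lost them as well (0.081, 0.105 and 0.0792), as without WT MLN replicate 2 (0.0535, 0.0522 and 0.0987). The effector and NK calls were also lost without WT PLN replicate 1 (0.0692 and 0.144) or WT MLN replicate 1 (0.144 and 0.13), the B cell call without AID KO PLN or AID KO MLN (0.193), and the NK call without uMT PLN or uMT MLN (0.0736) or any naive array (0.211 to 0.213). The type I interferon response list, MLN versus PLN, and the interferon-gamma response and antigen presentation list, MLN versus PLN, turned to -0.10 and -0.03 without AID KO PLN or AID KO MLN, and to -0.13 and -0.03 without uMT PLN or uMT MLN. In WT arrays the type I interferon response list was lower in MLN. Relative to each gene's mean over the total-cell arrays, its median was 0.002 and -0.06 in WT PLN and -0.42 and -0.45 in WT MLN. It was -0.21 in AID KO PLN, -0.08 in uMT PLN, 0.40 in AID KO MLN and 0.87 in uMT MLN. Its higher level in MLN therefore came from the knockout arrays only. Without 1 array, the count of 28 became 6 (WT PLN replicate 1 or WT MLN replicate 2), 3 (WT PLN replicate 2), 15 (WT MLN replicate 1) or 2 (AID KO PLN or AID KO MLN). Normexp gave 87 and the series matrix 61. P2rx7 kept its call in every case, and the other genes named for this comparison lost it without AID KO PLN and without AID KO MLN.

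Whether the knockout effect differs by site was tested with an interaction term, and 0 of 25387 features passed in limma (lowest adjusted p = 0.0637, 1085 at an unadjusted p under 0.05). On simulated data this test recovered 0 of 72 4-fold differences. The lowest p-values belonged to interferon-induced genes, which were higher in the knockouts in MLN than in PLN. The difference was 3.84 ± 0.16 for Rsad2 (adjusted p = 0.0637), 2.89 ± 0.15 for Ifit1 and 2.43 ± 0.15 for Oasl2 (both 0.089), and all 3 passed with normexp, where the Rsad2 log2 difference, knockout effect by site, had adjusted p = 0.00295 and the count was 24, against 17 in the series matrix. For knockout effect by site, the type I interferon response list was called, with 43 of 44 members higher, 41 up when adjusted over the list alone and a median of 1.16 (adjusted p = 2.39e-68; adjusted p = 0.149 with an estimated correlation). The interferon-gamma response list had a median of 0.51 with 10 up when adjusted over the list alone (adjusted p = 8.76e-19; adjusted p = 0.719 with an estimated correlation). Ly6a differed by 0.98 ± 0.19 (adjusted p = 0.691).

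The effect within each site was added after seeing this result. In knockouts versus WT, MLN (2 against 2 arrays), 43 features passed, 29 higher and 14 lower, and in PLN 0 passed in limma with 2231 at an unadjusted p under 0.05. In MLN the antiviral genes Ifi44 (at least 9.90-fold) and Rsad2 (3.37 ± 0.11, both adjusted p = 0.0187), Ifit3b (2.92 ± 0.16, adjusted p = 0.0196) and the GTPase gene Iigp1 (2.32 ± 0.14, adjusted p = 0.0243) rose. Of 44 type I interferon response genes 15 rose, 42 were up when adjusted over the list alone, and the median was 1.02 (adjusted p = 4.9e-45; adjusted p = 0.271 with an estimated correlation). The list median was 0.83 in AID KO MLN and 1.26 in uMT MLN against the WT array of the same slide, and -0.20 and -0.02 in the PLN arrays. Further lists were called in MLN. In PLN the lists called were immediate early and stress (-0.32, adjusted p = 8.09e-06), erythroid cells (1.36, 0.00123), proliferation (-0.14, 0.00126), type I interferon response (-0.11, 0.00898) and macrophages and monocytes (-0.35, 0.0439). With an estimated correlation their adjusted p was 0.647 or 0.996. Among the falls in MLN, Atf3, Vwa5b2 and Cyp2g1 were at least 3.76-fold, 2.85-fold and 1.73-fold lower (adjusted p = 0.0187, 0.0187 and 0.0351). Ly6a was higher by 1.26 and 1.74 in the 2 MLN pairs and just missed the threshold there (adjusted p = 0.0505). Without any 1 of the 12 arrays, the MLN count was 0, or 2 without AID KO PLN or uMT PLN. The type I interferon list call in MLN remained, with medians between 0.86 and 1.25. With matched pair blocks 0 features passed in MLN, so every call there was lost. The split was 99 higher and 31 lower with normexp and 91 and 24 in the series matrix.

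**Figure D3:**
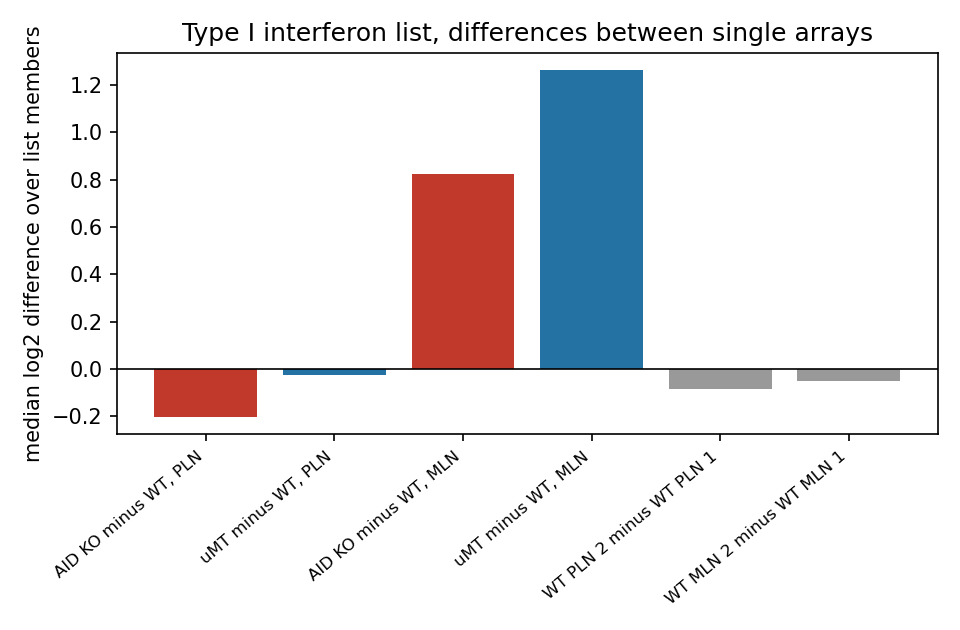
Bars give the median log2 difference over the 44 type I interferon response genes for each knockout array minus the WT array of its site and slide (red, AID KO; blue, uMT) and between the 2 WT arrays of a site (grey). The medians are -0.20 and -0.02 in PLN and 0.83 and 1.26 in MLN, for AID KO and uMT.

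Naive PLN cells sorted by Sca-1 were compared next (2 Sca1p against 2 Sca1m arrays). In Sca1p versus Sca1m 4 features passed, 3 higher and 1 lower, and 2128 had an unadjusted p under 0.05. Cxcr3, a chemokine receptor of effector and memory cells, rose by 2.13 ± 0.11 (adjusted p = 0.02), Cd163l1 at least 1.44-fold and Chst11 at least 1.73-fold (both adjusted p = 0.033), and the feature that fell has no gene name. Ly6a itself was higher by 3.67 ± 0.31 in both genotypes but missed the threshold (adjusted p = 0.071), and it passed with normexp (0.0129). Ly6c1 and Ly6c2, markers of memory-like cells, were higher by 1.56 ± 0.16 and 1.51 ± 0.17 (both adjusted p = 0.0884). Snrpn (1.67, adjusted p = 0.071), Tmem37 (1.22) and Prss12 (0.99, both 0.0884) were higher, and Plxdc2 (-1.50), Pdgfb (-1.40), Plxnd1 (-1.09), Cd200 (-1.81), Ndrg1 (-1.44), Gucy1b1 (-1.67), Klra8 (-1.24) and Maged1 (-1.16) were lower without passing, with adjusted p between 0.071 and 0.0884.

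By group, in Sca1p versus Sca1m the Ly6 family had a median of 0.41 with 5 of 9 up when adjusted over the list alone (adjusted p = 1.42e-05; adjusted p = 0.662 with an estimated correlation). Ly6a, whose product the cells were sorted on, has the largest change on this list, 3.67, so the sort fixed part of this call. Interferon-gamma response and antigen presentation genes were higher, with a median of 0.25 (adjusted p = 2.02e-05; adjusted p = 0.662 with an estimated correlation), a call lost without Sca1p or Sca1m AID KO (adjusted p = 0.195). In the effector and memory CD8 list, Sca1p versus Sca1m, 1 of 39 genes rose, 10 were up and 4 down when adjusted over the list alone, and the median was 0.09 (adjusted p = 0.0266; adjusted p = 0.662 with an estimated correlation), a call lost without Sca1p or Sca1m AID KO (adjusted p = 0.393) and without Sca1p or Sca1m uMT (0.0539 and 0.0538). The activation and inhibitory receptors list, Sca1p versus Sca1m, had a median of -0.24 with 3 down when adjusted over the list alone (adjusted p = 0.000376; adjusted p = 0.475 with an estimated correlation), a call also lost without Sca1p or Sca1m uMT (adjusted p = 0.0539 and 0.0538). Cholesterol synthesis genes (median -0.15, 0 of 17 higher, adjusted p = 0.000325; adjusted p = 0.662 with an estimated correlation) were lower, and the cholesterol synthesis list, Sca1p versus Sca1m, lost its call without Sca1p or Sca1m uMT (adjusted p = 0.438). Ribosomal protein genes were higher, at 0.16 (adjusted p = 2e-04; adjusted p = 0.714 with an estimated correlation), and the ribosomal proteins list, Sca1p versus Sca1m, lost its call without Sca1p or Sca1m AID KO (adjusted p = 0.594) and with normexp (0.482). Type I interferon response (0.20, 38 of 44 higher, adjusted p = 0.0398), proliferation (-0.09, 0.0172) and mucosal homing and residency genes (-0.09, 0.0213) were called too, with adjusted p = 0.947, 0.662 and 0.662 with an estimated correlation. With normexp the type I interferon response list, Sca1p versus Sca1m, the proliferation list, Sca1p versus Sca1m, and the mucosal homing and residency list, Sca1p versus Sca1m, lost their calls (adjusted p = 0.0631, 0.151 and 0.0822). All 3 were lost without Sca1p uMT (0.405, 0.822 and 0.438) or Sca1m uMT (0.404, 0.822 and 0.438), and the interferon and mucosal calls without Sca1p AID KO (0.277 and 0.0504) or Sca1m AID KO (0.276 and 0.0503). The count of Sca1p versus Sca1m was 0 without any total-cell array, 0 with the naive arrays fitted apart, and 165 without Sca1p uMT or Sca1m uMT. The split was 10 higher and 4 lower with normexp, 8 and 5 in the series matrix and 7 and 10 with quantile normalization.

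The 2 genotypes were compared in naive cells as well. In uMT versus AID KO, naive cells (2 against 2 arrays), Pianp was at least 62.7-fold lower in uMT by the brighter of its 2 probes (adjusted p = 0.00292) and Klrk1 at least 8.46-fold lower (adjusted p = 0.00602). The other Pianp probe stood at -3.56 and -3.16 in AID KO. Neither probe was above background in uMT. The Pianp log2 difference, uMT versus AID KO, naive cells, was -4.85 with the mean of both, which is therefore no measure of its size. Tshz3, Zfp541 and Ttc24 were higher by at least 3.81-fold, 3.09-fold and 1.97-fold (adjusted p = 0.0248, 0.00292 and 0.00358). Of the 88 features passed, 42 higher and 46 lower, 64 were below background on 1 side. Ly6a differed by -0.30 ± 0.31 (adjusted p = 0.943), and the immediate early and stress list had a median of 0.01 (adjusted p = 0.853). The lists of effector and memory CD8 (-0.18, adjusted p = 0.0233), interferon-gamma response and antigen presentation (-0.14, 0.0171), cholesterol synthesis (0.18, 0.0233) and ribosomal proteins (-0.08, 0.043) were called, each with adjusted p = 0.862 with an estimated correlation. The effector and memory CD8 list, uMT versus AID KO, naive cells, lost its call without each naive array (adjusted p = 0.388 for Sca1p AID KO, 0.0509 for Sca1m AID KO, 0.384 for Sca1p uMT and 0.0503 for Sca1m uMT). The interferon-gamma response and antigen presentation list, uMT versus AID KO, naive cells, lost it without Sca1p AID KO or Sca1p uMT (0.829 and 0.826), and the cholesterol synthesis list, uMT versus AID KO, naive cells, without Sca1m AID KO or Sca1m uMT (0.697 and 0.698). The ribosomal proteins list, uMT versus AID KO, naive cells, lost it without WT PLN replicate 1 (0.0547) or WT MLN replicate 2 (0.0633) and turned to 0.02 without Sca1p AID KO or Sca1p uMT and to 0.04 with normexp.

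In uMT versus AID KO, naive cells, the count was 32 and 47 without WT PLN replicates 1 and 2, 37 and 27 without WT MLN replicates 1 and 2, 37 without AID KO PLN or AID KO MLN, 44 without uMT PLN or uMT MLN, and 206 and 208 without Sca1m AID KO and Sca1m uMT. It was 0 with the naive arrays fitted apart. Tshz3 lost its call without each of the 8 total-cell arrays, and the other 4 genes kept theirs. The split was 11 higher and 6 lower in the series matrix.

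Whether the Sca1p difference depends on genotype rests on single arrays. In Sca1 difference by genotype 22 features passed, 12 higher and 10 lower in uMT than in AID KO, 17 of them below background on 1 side. Rpp38 had a lower Sca1p difference in uMT (-5.66 ± 0.33, adjusted p = 0.0451), from a high signal in Sca1m uMT. Among the 4 naive arrays, Entpd1, which encodes the ectonucleotidase CD39, was above background only in Sca1m AID KO, at -1.04, and Terc only in Sca1m uMT, at 4.83 (both adjusted p = 0.0451). Fgd6 was not above background in Sca1p AID KO (adjusted p = 0.0451), and Prickle4 was above background only in Sca1p AID KO and Sca1m uMT, at -2.71 and -3.47 (adjusted p = 0.0268), so no size is given for these 4. Ly6a differed by -0.34 ± 0.65 (adjusted p = 0.901). Without any 1 of the 8 total-cell arrays, which alone carry the spread here, the count of Sca1 difference by genotype was 0, or 2 without uMT PLN or uMT MLN. It was 97 with normexp and 70 in the series matrix.

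Genes ranked by the moderated statistic of Sca1p versus Sca1m, where only 4 features passed, were then tested in total knockout cells. The 100 with the highest statistic had a median of -0.0071 in knockouts versus WT (adjusted p = 0.822). The 100 with the lowest had 0.0145 (adjusted p = 0.601). In arrays labelled AID KO the medians were -0.0134 (adjusted p = 0.743) and 0.1207 (adjusted p = 0.00532; adjusted p = 0.465 with an estimated correlation), and in uMT they were 0.0146 (0.934) and -0.0469 (0.831). With 50 genes in place of 100, a call was gained for Sca1 gene lists in total knockout cells: higher in Sca1p, uMT versus WT, at 0.166 (adjusted p = 0.023), and for Sca1 gene lists in total knockout cells: lower in Sca1p, knockouts versus WT, at 0.1147 (0.00383). Across genes, Sca1p differences correlated with the knockout differences at -0.0001, with those of AID KO at -0.0208 and with those of uMT at 0.0204. Most members of the lists were not shown to differ between the fractions, and the ranking statistic shares its residual spread with the total-cell arrays. The list medians therefore cannot decide whether genes that do differ by Sca-1 change in the knockouts.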

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

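The tests of explanations in this part were chosen only after the results had been seen. The results here are differences between groups that passed a test of the difference itself, which is either the direct comparison of the 2 genotypes or an interaction term. In uMT versus AID KO, total cells, 80 features differed. The named genes were Klk1b22 (7.08), Klk1b27 (at least 25.3-fold), Klk1b24 (5.67), Dusp1 (2.30), Klf4 (1.91), Fos (1.76) and Cd69 (1.40), higher in uMT, and Pianp (-6.17) and Ppfibp1 (-3.14), lower. The list medians were 0.62 for immediate early and stress, 0.30 for type I interferon response, -0.15 for proliferation, -0.31 for B cells, 0.072 for NK and innate-like lymphocytes and 1.98 for erythroid cells. Of these, the type I interferon response median turned negative at least once with 1 array left out. The NK and innate-like lymphocytes median turned negative with series matrix values and with features well above background on every array. By site, the knockout effect was larger in MLN for the lists of type I interferon response (1.16), interferon-gamma response and antigen presentation (0.51), Ly6 family (0.38), ribosomal proteins (0.16) and effector and memory CD8 (0.12). The ribosomal median turned with normexp, quantile normalization and series matrix values, and its test direction turned at least once with 1 array left out. For Sca1 difference by genotype 22 features passed, among them Rpp38 (-5.66), and, below background on at least 1 of the 4 arrays and so without a size, Fgd6, Entpd1 and Terc (each adjusted p = 0.0451) and Prickle4 (adjusted p = 0.0268). These list calls were made at the preset correlation, and none held with the estimated one.

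The first pattern is the rise of interferon genes in the 2 knockout MLN arrays. Relative to each gene's mean over the total-cell arrays, the list median was 0.40 in AID KO MLN and 0.87 in uMT MLN. It was -0.42 and -0.45 in the 2 WT MLN arrays and 0.002 and -0.06 in the 2 WT PLN arrays. WT MLN was thus below WT PLN, which makes up part of the gap to the knockouts in MLN. Slide or scan batch is argued against by the lower of the 2 medians against the WT array of the same slide, 0.83. Erythroid cells are argued against by their median of -1.22 in AID KO MLN and, for uMT MLN with 1.62, by a median of 1.45 in uMT PLN, where the interferon list was at -0.02. Other immune or stromal cells cannot be told apart from a change in the T cells, since the highest medians of their lists, 0.47 (standard error 0.19) for CD4 T cells in AID KO MLN and 0.30 (0.24) for stroma and endothelium in uMT MLN, spread too widely over few markers beside 0.83 and 1.26 for the interferon list. These standard errors are taken over the markers of 1 pair of arrays and not over samples. In AID KO MLN 6 of the 8 CD4 T cell markers were higher, but Cd4 itself was lower, at 0.39 against 0.63 in WT. An effect of the genotype at this site and an infection or other exposure of the mice used for these 2 samples both remain open and untested, with 1 array per genotype and site.

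The second pattern is the fall of immediate early genes in the total-cell arrays labelled AID KO. For uMT versus AID KO, the list median was 0.0119 in naive cells, with 11 of 22 genes higher, and 0.62 in total cells, with 20 of 22 higher. For these arrays, this argues against an effect of the genotype alike in naive and total cells. The standard error of 0.12 in naive cells is taken over the 22 genes. It does not measure the spread between samples, of which each side has 2. Slide or scan batch is argued against by the smaller of the 2 medians against the WT array of the same slide, -0.43. Handling of single samples cannot be told apart from an effect of the genotype in total cells, because each genotype and site has 1 array, and the 2 WT arrays of a site differed by at most 0.077.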

How the results depend on the processing

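The single coefficient for both knockouts and the effects within each site were tests chosen after seeing the data, and the other alternatives were planned. Across alternatives other than left-out arrays, named genes kept direction and side of the threshold in 897 cases, lost the call in 182, gained it in 106 and moved in 3, and lists kept theirs in 562, lost it in 85 and turned in 11. With 1 array left out, named genes kept it in 951 cases, lost it in 585, gained it in 6 and moved in 10, and lists kept it in 625, lost it in 123 and turned in 20. Except for the fewer samples or features of some alternatives, the cause was not tested. A lone sample is assumed to vary like the other groups. The matched pair block gave no value for MLN versus PLN, leaving out a naive array gave none for Sca1 difference by genotype, and the slide and pair alternatives concern total cells only. Genes near background carry bounds, so signal over background limits the size of their differences.

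Counts of calls moved as follows, beside 141 for knockouts versus WT, 229 for AID KO versus WT, 9 for uMT versus WT, 80 for uMT versus AID KO, total cells, 28 for MLN versus PLN, 0 for knockout effect by site, 4 for Sca1p versus Sca1m, 88 for uMT versus AID KO, naive cells, 22 for Sca1 difference by genotype, 0 for knockouts versus WT, PLN, and 43 for knockouts versus WT, MLN. In this order they were 414, 501, 63, 170, 87, 24, 14, 53, 97, 13 and 130 with normexp and quantile, 541, 578, 73, 144, 61, 17, 13, 17, 70, 8 and 115 with series matrix values, 534, 574, 91, 183, 73, 18, 22, 24, 39, 10 and 113 with features well above background on all 12 arrays, and 584, 674, 139, 246, 127, 27, 29, 55, 6, 26 and 214 in eBayes with an intensity trend. With slide as a random block they were 333, 425, 72, 151, 75 and 15 for the first 6, then 10 and 122 for PLN and MLN. With no filter on dim probes they were 6, 50, 0, 18 and 16 for the first 5, 0 for Sca1p versus Sca1m, 690 for Sca1 difference by genotype and 0 for MLN. With quantile normalization they were 30 for uMT versus WT, 17 for Sca1p versus Sca1m, 34 for Sca1 difference by genotype and 1 for PLN. The first 4 were 17, 85, 2 and 30 with no slide term and 11, 15, 5 and 1 with a matched pair block, which left 0 for MLN. With total and naive arrays fitted apart, knockouts versus WT gave 46, uMT versus AID KO in total cells 35, and Sca1p versus Sca1m, uMT versus AID KO in naive cells and the MLN effect 0. One coefficient for both knockouts gave 15, and own WT arrays only gave a similarity of 0.241.

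Leaving out 1 array, the counts ranged from 0 to 46 for knockouts versus WT, 1 to 171 for AID KO versus WT, 0 to 8 for uMT versus WT, 1 to 35 for uMT versus AID KO in total cells, 2 to 24 for MLN versus PLN, 0 to 0 for knockout effect by site, 0 to 165 for Sca1p versus Sca1m, 27 to 208 for uMT versus AID KO in naive cells, 0 to 2 for Sca1 difference by genotype, 0 to 0 for PLN and 0 to 2 for MLN.

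The next values are those of Sca1 gene lists in total knockout cells: higher in Sca1p, knockouts versus WT, then Sca1 gene lists in total knockout cells: higher in Sca1p, AID KO versus WT, then Sca1 gene lists in total knockout cells: higher in Sca1p, uMT versus WT. The medians were 0.092, -0.0134 and 0.166 (adjusted p = 0.023, where the test direction turned while the median stayed positive) with lists of 50 genes, -0.0063, -0.0015 and 0.0135 with lists of 200 genes, 0.028, 0.0317 and 0.0372 with normexp, 0.0269, 0.0068 and 0.0568 with quantile normalization, and 0.0061, 0.0254 and 0.0301 with the mean of all probes. With no filter on dim probes they were 0.0132 in knockouts and 0.065 in uMT, and the correlation over genes in place of lists was -0.0001, -0.0208 and 0.0204. A call was gained for Sca1 gene lists in total knockout cells: lower in Sca1p, knockouts versus WT, with lists of 50 genes (0.1147), normexp (0.0593) and quantile normalization (0.0594), and Sca1 gene lists in total knockout cells: lower in Sca1p, uMT versus WT, had 0.0171, 0.0082 and 0.0134 there and 0.0099 with lists of 200 genes.

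List medians that turned were those of the ribosomal proteins list, knockout effect by site (-0.0133 with normexp, -0.0038 with quantile normalization, -0.0072 with series matrix values), of the ribosomal proteins list, uMT versus AID KO, naive cells (0.0444, 0.0306 and 0.0324 in that order) and of the NK and innate-like lymphocytes list, uMT versus AID KO, total cells (-0.0436 with series matrix values, -0.0535 with all 12 arrays above background). The direction of the test turned while the median stayed positive for the ribosomal proteins list, knockouts versus WT, MLN (0.0051 with quantile normalization, 0.0021 with series matrix values) and the NK and innate-like lymphocytes list, uMT versus WT (0.078 with series matrix values).

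With 1 array left out, the test direction turned at least once for these list medians, which ranged from -0.3975 to 0.9133 for the type I interferon response list, uMT versus AID KO, total cells, from -0.1348 to 0.3832 for the type I interferon response list, MLN versus PLN, from -0.0108 to 1.2351 for the type I interferon response list, uMT versus WT, from -0.0437 to 0.4345 for the interferon-gamma response and antigen presentation list, uMT versus WT, from -0.1252 to 0.3339 for the ribosomal proteins list, uMT versus WT, from -0.0317 to 0.1465 for the interferon-gamma response and antigen presentation list, MLN versus PLN, from -0.1592 to 0.4932 for the ribosomal proteins list, knockout effect by site, from -0.1642 to 0.4596 for the ribosomal proteins list, knockouts versus WT, MLN, from -0.7417 to 0.0612 for the plasma cells and switched immunoglobulin list, knockouts versus WT, MLN, from -0.2458 to 0.0034 for the type I interferon response list, knockouts versus WT, PLN, from -0.1953 to 0.805 for the type I interferon response list, AID KO versus WT, from 0.0148 to 0.3544 for the interferon-gamma response and antigen presentation list, AID KO versus WT and from -0.1752 to 0.0166 for the ribosomal proteins list, uMT versus AID KO, naive cells.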

Other observations

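The splits of samples in this part were tests chosen only after the results had been seen. In total cells, Ly6a and the type I interferon response list were both higher in the knockout MLN arrays, while in the PLN arrays only Ly6a was. Against the WT array of the same slide, Ly6a was higher by 0.49 in AID KO PLN, 0.56 in uMT PLN, 1.26 in AID KO MLN and 1.74 in uMT MLN, and the list median was -0.20, -0.02, 0.83 and 1.26 in that order. In naive cells the sort moved Ly6a by 3.50 and 3.83 while the list median moved by 0.20 over both genotypes, with 38 of 44 members higher (adjusted p = 0.0398; adjusted p = 0.947 with an estimated correlation).

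Erythroid markers differed between arrays of 1 group by up to 1.51, the gap of the 2 WT PLN arrays, and were 1.45 and 1.62 higher in uMT PLN and MLN and -1.22 in AID KO MLN against the WT array of the same slide. Uneven spots made up 0.351% of the Sca1p AID KO array and 0.218% of the Sca1m AID KO array, and at most 0.0191% of a total-cell array.

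Each even split of the 8 total-cell arrays, 35 in all, was fitted with 1 coefficient. For knockouts versus WT 15 features passed. Of the 35 splits 3 gave at least as many, namely the real split, the split by slide, which was the highest with 4709, and the split by site with 32, and no split that follows none of these gave more than 4. For MLN versus PLN 28 passed. Again 3 splits gave at least as many, namely the real split, the split by slide, the highest with 5808, and the split by knockout with 37, and no split that follows none of these gave more than 15. The other splits as large follow known structure and are no chance splits, so the share of 3 in 35 cannot decide whether chance gave either count. The slides are a structure of the samples that the fit removes, and the matched pair block called 11 features for knockouts versus WT, 9 of them among the 141.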
